A study of Homo sapiens with 48 samples.

How the data were processed

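The authors deposited 1 file per library holding, per the file headers, the expected counts (expected_counts) of RSEM for 387954 transcripts. The submitters' processing notes name RSEM, Picard and GRCh38 without versions, and the role of Picard, the aligner, the annotation release and the counting strand are not given in the sources used here. Per the labels, RNA was isolated with the Direct-zol RNA MiniPrep kit and libraries were made with the TruSeq Stranded mRNA kit. Expected counts were summed over the transcripts of each of 78894 gene identifiers and rounded. Of these, 61463 have a symbol, and 322 symbols stand on more than 1 identifier. A gene's transcript length in a library is the count-weighted mean of RSEM's transcript lengths.

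Groups and replicate numbers come from the sample labels. In each line, edgeR 4.0.16 in R 4.3.3 fitted 1 mean per group to all 24 libraries, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, and contrasts were tested with the quasi-likelihood test (two-sided) with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.161 in SKMEL173 and 0.177 in SKMEL30, with 18 residual degrees of freedom each. SE is the absolute log2 change over the square root of F. Differences between lines came from a fit of all 48 libraries (17572 genes, 36 degrees of freedom). A gene was called with both siRNAs when each passed in the same direction.

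The comparisons, tests, 12 groups, gene lists, rule for named genes and planned settings were fixed before the data were examined. Named genes have a symbol, are protein coding and have an average log2 CPM of at least 0. They are NRAS and DGKH, then per target the 10 that rose and 10 that fell in all 4 contrasts of its siRNAs in the 2 lines with the largest smallest change, 5 and 5 per target and line, up to 4 members per list called with both siRNAs, 5 and 5 for siCntrl against Untreated in both lines, 5 and 5 for each difference between lines, 10 called in all 8 contrasts, 5 and 5 for siDGKH against siNRAS, and 3 and 3 for each pair of siRNAs. MAPKAPK2 is the 1 gene named outside this rule, after its values were seen, because it and PFKFB4 alone were called in all 8 contrasts against Untreated. Some genes the rule takes are not reported here.

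The 32 gene lists cover ERK-induced genes, G1/S, G2/M, p53 targets, pigmentation, neural crest identity, the undifferentiated state, sterol and fatty acid synthesis, diacylglycerol kinases, phosphatidic acid and phosphoinositide metabolism, RAS and RAF paralogs, protein kinase C, ATF4 targets, the unfolded protein response, interferon response, antigen presentation, NF-kB, lysosome, glycolysis, oxidative phosphorylation, MYC and ribosome biogenesis, the BCL2 family, matrix and adhesion, the RNAi machinery, histones, mitochondrial mRNAs and markers of keratinocytes, fibroblasts, leukocytes, endothelium and epithelium. They were tested with camera of limma 3.58.1 on the mean of a target's 2 siRNAs, with the preset correlation of 0.01 and with the correlation estimated per list.

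The replicate numbers come from the labels. Deviations from the group mean correlated more between libraries of the same number than of other numbers, on average, in 15 of 15 pairs of groups in SKMEL173 over genes with log2 CPM over 1 and 15 of 15 over all tested genes. In SKMEL30 this held in 13 of 15 and 14 of 15 (15 of 15 and 15 of 15 without the 2 short-transcript libraries). Every same-number correlation exceeded 0.1 in 15 of 15 and 10 of 15 pairs of groups in SKMEL173, and in 6 of 15 and 5 of 15 in SKMEL30 (11 of 15 and 10 of 15 without those libraries, for groups with at least 3 numbers in common). Both gene sets were seen, and the effect of the block was known, when this was written, so values with the replicate number as a block stand beside those without it. Other settings were DESeq2 1.42.0 size factors and Wald test, no or a stricter low-count filter (CPM of at least 1 in 4 libraries), Untreated as reference, a fit of only the groups compared, and each library left out in turn. Settings that leave out the 2 short-transcript libraries of SKMEL30 were chosen after seeing the data.

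The procedure was tested on simulated data. For a single siRNA, 59% of genes changed 1.5-fold and 86% of genes changed 2-fold were called in SKMEL173, and 41% and 77% in SKMEL30. With both siRNAs it was 50% and 86%, and 29% and 70%, with at most 6 false calls. Seed words were sought as 7-mers in the 3′ UTRs of GENCODE 29 (12916 of 13052 tested coding genes in SKMEL173, 12247 of 12363 in SKMEL30): log2 changes were turned to normal scores within 10 bins of UTR length, the word with the lowest z among words in at least 50 genes was taken in SKMEL173, and its rank among all 16384 words was read in SKMEL30. A planted word ranked first in 17 of 20 simulated runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Raw reads were not used here.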

Results

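RNA was sequenced from 48 libraries of the NRAS-mutant human melanoma lines SKMEL173 and SKMEL30, collected 72 h after transfection. Each line had 6 groups of 4 libraries. 2 groups had an siRNA against NRAS (siNRAS_05 and siNRAS_06) and 2 an siRNA against DGKH (siDGKH_05 and siDGKH_06). The others were a control siRNA (siCntrl) and cells without siRNA, labelled Untreated in the sample labels and mock in the design text. Whether Untreated cells received transfection reagent is not clear from the labels, so differences from Untreated can hold its effect. NRAS encodes a small GTPase upstream of RAF kinases. DGKH encodes diacylglycerol kinase eta, which phosphorylates diacylglycerol to phosphatidic acid. NRAS is ENSG00000213281.5 on chromosome 1 (114704469 to 114716894, minus strand). DGKH is ENSG00000102780.17 on chromosome 13 (42040036 to 42256578, plus strand) in GRCh38 with GENCODE 29 gene models. Expected counts summed over a library's genes ran from 23.1 to 37.6 M (median 28.5 M). After the low-count filter 16575 genes were tested in SKMEL173 and 15244 in SKMEL30. The labels do not state that the libraries of a group came from separate cultures. The p-values measure the spread between these libraries, which may be technical. No 2 libraries of a group were copies of each other: over the 72 within-group pairs, chi-square per gene ran from 9.64 to 262.

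2 of the SKMEL30 libraries held shorter transcripts than the rest of their groups. The count-weighted mean transcript length was 2239 nt in siCntrl replicate 2 (the other 3 siCntrl libraries 2984 to 3094 nt). It was 2586 nt in siNRAS_06 replicate 3 (the others of that group 2960 to 3059 nt). The main SKMEL30 gene counts that rest on siCntrl or siNRAS_06 are therefore also given without these 2 libraries, an alternative chosen after seeing the data.

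To measure the knockdown, NRAS and DGKH were compared with siCntrl in each line. In SKMEL173, NRAS fell from 439 ± 35.8 CPM (counts scaled to library size, mean ± SD, n = 4) with siCntrl to 57.8 ± 13.1 with siNRAS_05 and 41.0 ± 10.2 with siNRAS_06. That is 86.8% and 90.7% lower (log2 change ± SE -2.93 ± 0.16 and -3.42 ± 0.16, adjusted p = 2.53e-11 and 2.93e-12, edgeR quasi-likelihood test). In SKMEL30 NRAS fell from 198 ± 46.1 to 67.2 ± 21.3 and 44.6 ± 23.3, or 66.1% and 77.5% (-1.56 ± 0.25 and -2.15 ± 0.26, adjusted p = 0.000241 and 4.96e-06). DGKH in SKMEL173 fell from 32.5 ± 5.00 to 7.36 ± 0.448 with siDGKH_05 and 14.6 ± 2.30 with siDGKH_06, or 77.4% and 55.2% (-2.14 ± 0.18 and -1.16 ± 0.17, adjusted p = 4.94e-09 and 1.2e-05). In SKMEL30 DGKH went from 34.8 ± 13.4 to 17.3 ± 2.97 with siDGKH_05, 50.3% lower (-1.01 ± 0.22, adjusted p = 0.00473).

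siDGKH_06 did not pass the test for DGKH in SKMEL30, where the level was 29.1 ± 3.70 CPM (-0.26 ± 0.22, adjusted p = 0.403). Without the 2 short-transcript libraries the DGKH change was -0.49 (adjusted p = 0.00465). Without siCntrl replicate 2 alone it was -0.50 (adjusted p = 0.0198). Without siCntrl replicates 1, 3 and 4 it was -0.21, -0.07 and -0.21 (adjusted p = 0.546, 0.838 and 0.538), and against Untreated -0.45 (0.18). siDGKH_06 also lowered NRAS in SKMEL173 by 36.1% (-0.65 ± 0.15, adjusted p = 0.00133). NRAS was 0.33 ± 0.15 higher in siCntrl than in Untreated there (adjusted p = 0.318), and against Untreated the change with siDGKH_06 was -0.31 (0.0985). With siDGKH_05 in SKMEL173 NRAS stood at -0.24 ± 0.15 (adjusted p = 0.258). It stood at 0.12 ± 0.25 and -0.33 ± 0.25 with siDGKH_05 and siDGKH_06 in SKMEL30 (adjusted p = 0.807 and 0.356). In an exact two-sided permutation test of 4 against 4 libraries the smallest p that can be reached is 0.0286. NRAS reached it with both siNRAS siRNAs in both lines, as did NRAS and DGKH with both siDGKH siRNAs in SKMEL173. DGKH in SKMEL30 gave exact p = 0.114 with siDGKH_05 and 0.457 with siDGKH_06. Adjusted over the 16 exact tests, the smallest p becomes 0.0572. Reads shared between NRAS or DGKH and their paralogs or pseudogenes were assigned by the counting software, and this was not analysed here.

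**Figure D1:**
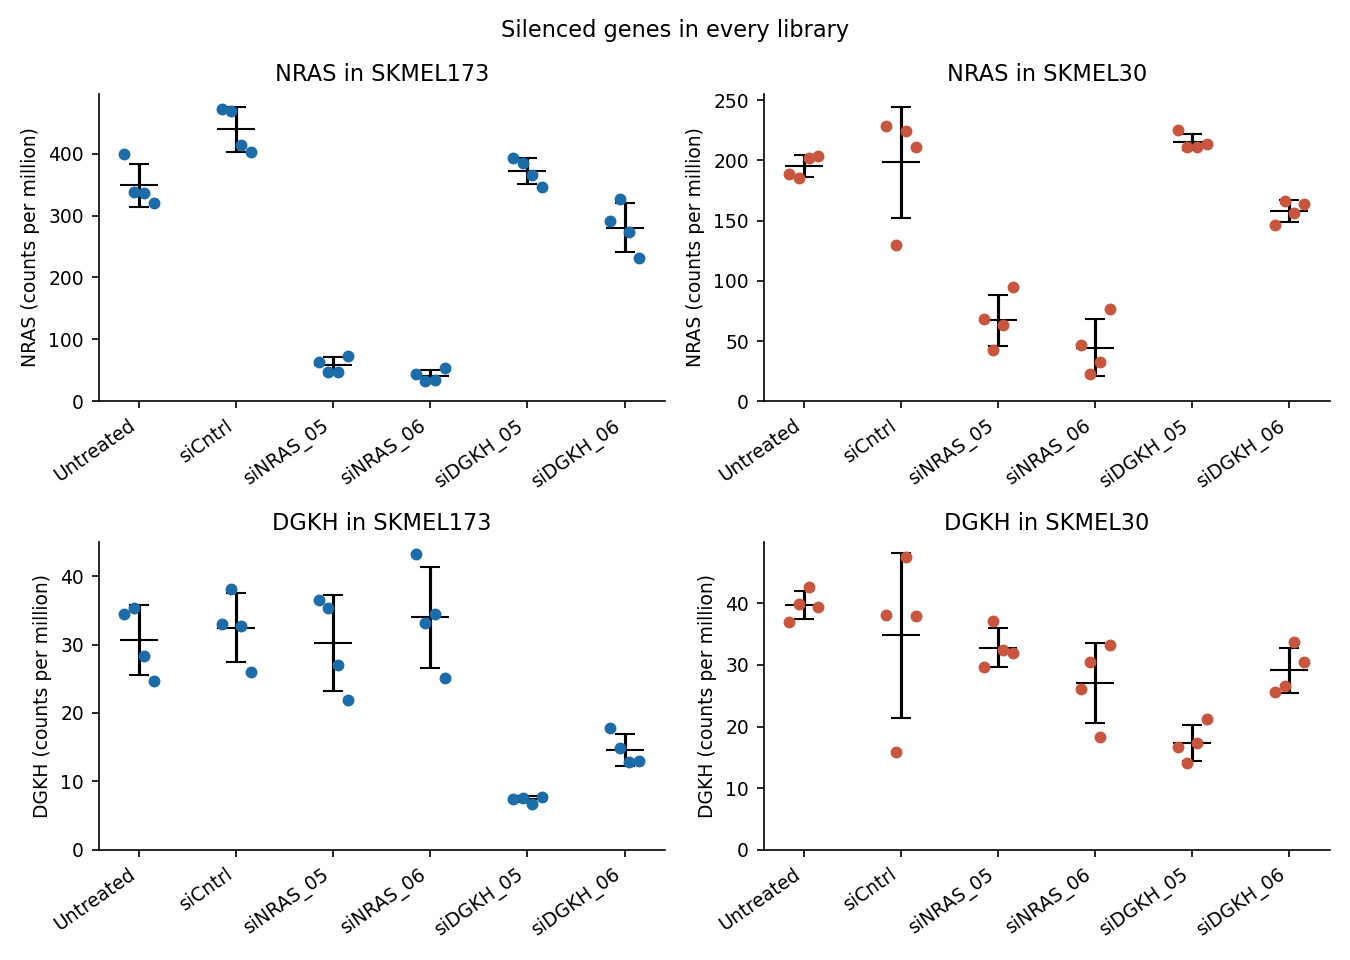
NRAS and DGKH CPM in every library of each group, with mean ± SD (n = 4).

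With NRAS silenced, 10 genes stood out as fallen furthest in both lines. CXCL8, a neutrophil chemokine, changed by log2 -3.70 ± 0.63 and -3.82 ± 0.64 in SKMEL173 and by -2.31 ± 0.72 and -2.78 ± 0.74 in SKMEL30 with siNRAS_05 and siNRAS_06 (± SE, 4 libraries against 4, largest adjusted p = 0.0372). TMEM158, a membrane protein induced by RAS, changed by -2.04 ± 0.37 and -2.31 ± 0.38 in SKMEL173 and by -2.58 ± 0.31 and -2.43 ± 0.31 in SKMEL30 (0.000415). LIF, a cytokine of the interleukin 6 family, changed by -2.01 ± 0.24 and -1.95 ± 0.24 in SKMEL173 and by -2.31 ± 0.21 and -2.40 ± 0.21 in SKMEL30 (5.29e-06). The immediate early gene IER3 changed by -1.68 ± 0.17 and -1.79 ± 0.17 in SKMEL173 and by -2.20 ± 0.24 and -2.19 ± 0.24 in SKMEL30 (1.81e-06). GDF15, a stress-induced member of the TGF-beta superfamily, MYEOV, SERPINB2, an inhibitor of urokinase, DKK1, an inhibitor of WNT signalling, and UCN2, a peptide hormone, fell with both siRNAs in both lines as well.

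Of the genes that rose in both lines, GALNT3, an enzyme of mucin-type O-glycosylation, changed by 2.87 ± 0.60 and 3.08 ± 0.60 in SKMEL173 and by 2.40 ± 0.24 and 2.55 ± 0.25 in SKMEL30 (largest adjusted p = 0.00145). LRRC39 changed by 2.17 ± 0.32 and 2.41 ± 0.32 in SKMEL173 and by 2.87 ± 0.48 and 3.17 ± 0.48 in SKMEL30 (0.000306). BCAN, which encodes the proteoglycan brevican, changed by 2.17 ± 0.43 and 1.92 ± 0.43 in SKMEL173 and by 1.84 ± 0.37 and 2.13 ± 0.37 in SKMEL30 (0.00209). PAQR8, a membrane progesterone receptor, changed by 1.37 ± 0.20 and 1.53 ± 0.20 in SKMEL173 and by 2.16 ± 0.22 and 2.21 ± 0.22 in SKMEL30 (3.03e-05). TMCC3, FAXDC2, PSKH1, SMAD9, DTNA and DIPK1A rose too. All 20 of these genes lay on the called side of the siCntrl mean in all 16 siNRAS libraries. For 19 of them the siNRAS and siCntrl libraries did not overlap within a line. They are the 10 highest and 10 lowest by the smallest of their 4 changes, NRAS itself included. Averaged over the 2 siRNAs and set against Untreated, 10 of the 10 genes that fell still passed in SKMEL173 and 9 in SKMEL30, and 5 and 9 of the 10 that rose. TMEM158 then stood at -1.32 in SKMEL173 and -0.82 in SKMEL30 (adjusted p = 0.00525 and 0.0547). PSKH1 stood at 0.31 in SKMEL173 and 0.34 in SKMEL30 (adjusted p = 0.106 and 0.0717), and was lower in siCntrl than in Untreated.

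**Figure D2:**
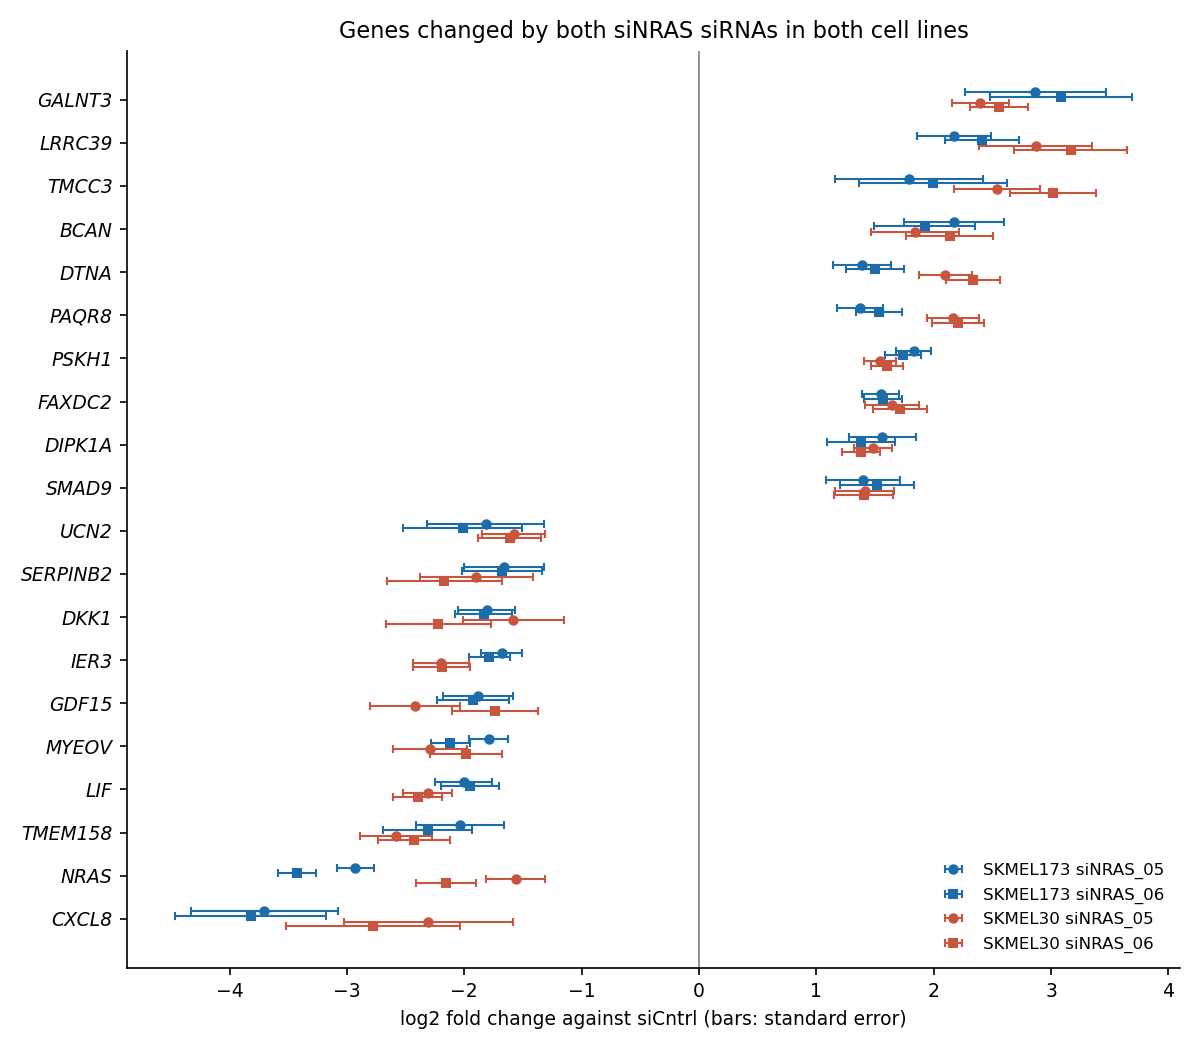
log2 change against siCntrl (± SE, 4 libraries against 4) of the 10 genes that rose most and the 10 that fell most with both NRAS siRNAs in both lines.

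Within single lines other genes stood out. In SKMEL173, F2RL1, a protease-activated receptor, changed by -2.45 ± 0.40 and -2.75 ± 0.41 with siNRAS_05 and siNRAS_06. EGR1, an ERK-induced transcription factor, changed by -2.27 ± 0.25 and -2.42 ± 0.25, and STC1, a secreted glycoprotein, by -2.23 ± 0.56 and -2.41 ± 0.56. PRICKLE1, a planar cell polarity gene, rose by 2.27 ± 0.43 and 2.73 ± 0.43 (largest adjusted p of these = 0.00612). In SKMEL30, NPPC, the C-type natriuretic peptide, changed by -2.89 ± 0.41 and -3.13 ± 0.42 and ANKRD1, a YAP target, by -2.63 ± 0.43 and -3.55 ± 0.47. SHISA2 changed by -2.52 ± 0.35 and -2.31 ± 0.35 and HAS2, a hyaluronan synthase, by 2.22 ± 0.28 and 2.31 ± 0.28 (largest adjusted p of these = 0.000241). All 10 genes taken by this rule in SKMEL173 and all 10 in SKMEL30 had their 8 siNRAS libraries on one side of every siCntrl library of the line. Against Untreated, 5 of 5 that fell and 3 of 5 that rose passed in SKMEL173, and 4 and 5 in SKMEL30 (mean of the 2 siRNAs). The median of those that fell in SKMEL30 was then -1.36 (against siCntrl -2.51). A gene past the threshold in one line only is not thereby shown to differ between lines.

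Of the fixed gene lists, the genes induced by ERK signalling moved down against the other genes, with a median log2 change over the 2 siRNAs of -0.88 in SKMEL173 (adjusted p = 3.94e-09, or 0.0131 with estimated correlation). The SKMEL30 median was -1.04 (adjusted p = 4.3e-16, or 0.00883 with estimated correlation). 14 of its 22 genes fell in SKMEL173 and 17 in SKMEL30 (14 down and 1 up, and 17 down and 1 up, adjusted within the list). CCND1, encoding cyclin D1, stood at -1.46 ± 0.12 and -1.53 ± 0.12 in SKMEL173 and -1.55 ± 0.17 and -1.80 ± 0.17 in SKMEL30. FOSL1, an AP-1 factor, stood at -2.13 ± 0.28 and -2.31 ± 0.28 in SKMEL30. The melanocyte differentiation and pigment genes moved up, with a median of 0.45 in SKMEL173 (adjusted p = 0.0011, or 0.403 with estimated correlation). In SKMEL30 it was 0.47 (adjusted p = 3.85e-10, or 0.00883 with estimated correlation). 6 of 20 rose and 1 fell in SKMEL173. In SKMEL30, 14 of 21 rose and 1 fell (6 and 1, and 16 and 2, adjusted within the list). CAPN3, a calpain protease, stood at 0.87 ± 0.15 and 0.81 ± 0.15 in SKMEL173 and 0.90 ± 0.12 and 1.16 ± 0.13 in SKMEL30. DCT, a melanin synthesis enzyme, stood at 1.53 ± 0.19 and 1.69 ± 0.20 in SKMEL30. Genes of the undifferentiated or invasive melanoma state moved down, with a median of -0.79 in SKMEL173 (adjusted p = 7.15e-06, or 0.0986 with estimated correlation). It was -0.62 in SKMEL30 (adjusted p = 0.000213, or 0.427 with estimated correlation). 12 of 20 and 7 of 16 fell (12 and 9 adjusted within the list). They include PLAUR, the urokinase receptor, in SKMEL30 (-1.65 ± 0.29 and -1.94 ± 0.29). No gene of this list rose. Every gene named with a list here and below was called with both siRNAs in the line given.

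Genes of MYC and ribosome biogenesis also moved down, with a median of -0.59 in SKMEL173 (adjusted p = 6.87e-16, or 0.0986 with estimated correlation). The SKMEL30 median was -0.27 (adjusted p = 2.96e-06, or 0.14 with estimated correlation). 24 of 26 fell in SKMEL173 and 13 in SKMEL30 (24 and 16 adjusted within the list), and none rose. RRS1, a ribosome assembly factor, stood at -0.78 ± 0.12 and -0.90 ± 0.12 in SKMEL173 and -0.55 ± 0.11 and -0.49 ± 0.11 in SKMEL30. Glycolysis and hypoxia genes had a median of -0.27 in SKMEL173 (adjusted p = 2.07e-07, or 0.135 with estimated correlation). In SKMEL30 it was -0.14 (adjusted p = 0.000483, or 0.064 with estimated correlation). 14 and 5 of 24 fell (17 and 6 adjusted within the list). The glucose transporter SLC2A3 stood at -1.45 ± 0.13 and -1.51 ± 0.13 in SKMEL173 and -1.39 ± 0.18 and -1.45 ± 0.18 in SKMEL30. SLC2A3 was higher in siCntrl than in Untreated, as given below, and against Untreated its mean change was -0.28 in SKMEL173 and -0.32 in SKMEL30 (adjusted p = 0.0774 and 0.25). VEGFA, an angiogenic growth factor, stood at -1.27 ± 0.14 and -1.39 ± 0.14 in SKMEL173 and -0.79 ± 0.16 and -0.91 ± 0.16 in SKMEL30. G1/S and DNA replication genes had a median of -0.23 in SKMEL173 (adjusted p = 0.015, or 0.78 with estimated correlation). It was -0.22 in SKMEL30 (adjusted p = 0.000367, or 0.305 with estimated correlation). 10 of 26 fell and 1 rose in SKMEL173, and 12 fell and 1 rose in SKMEL30 (13 and 2, and 13 and 1, adjusted within the list). UHRF1, which maintains DNA methylation at replication, stood at -0.51 ± 0.17 and -0.80 ± 0.18 in SKMEL173 and GINS2, of the replicative helicase, at -0.62 ± 0.16 and -0.60 ± 0.16 in SKMEL30.

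Further lists passed in SKMEL173. Sterol synthesis genes moved up (median 0.28, adjusted p = 0.000176, or 0.349 with estimated correlation, with 8 of 22 rising and 0 falling, 10 and 0 adjusted within the list). HMGCS1, an early enzyme of the pathway, stood at 0.89 ± 0.21 and 1.61 ± 0.21. Lysosome and autophagy genes moved up (median 0.17, adjusted p = 0.00266, or 0.349 with estimated correlation, with 11 of 29 rising and 2 falling, 13 and 2 adjusted within the list). RRAGD, a GTPase that recruits mTORC1 to lysosomes, stood at 1.17 ± 0.14 and 1.19 ± 0.14. Neural crest factors moved up (median 0.34, adjusted p = 0.0115, or 0.135 with estimated correlation, with 6 of 12 rising and 0 falling, 6 and 0 adjusted within the list). SOX10, a transcription factor of the melanocyte lineage, stood at 0.61 ± 0.20 and 0.77 ± 0.20 and ERBB3, a receptor for neuregulins, at 0.81 ± 0.15 and 0.51 ± 0.15. Genes of the unfolded protein response moved down (median -0.29, adjusted p = 0.0146, or 0.752 with estimated correlation, with 7 of 18 falling and 0 rising, 8 and 0 adjusted within the list). The disulfide isomerase PDIA4 stood at -0.45 ± 0.12 and -0.54 ± 0.12. p53 targets and CDK inhibitors moved down (median -0.25, adjusted p = 0.0328, or 0.349 with estimated correlation, with 8 of 20 falling and 4 rising, 10 and 4 adjusted within the list). CDKN1A, encoding p21, stood at -0.91 ± 0.11 and -0.69 ± 0.11. The p53 call was lost without replicate 4 (adjusted p = 0.0679). Against Untreated the p53 list turned to the other direction (adjusted p = 0.986).

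In SKMEL30 the NF-kB targets and cytokines moved down (median -0.55, adjusted p = 0.0152, or 0.133 with estimated correlation, with 4 of 12 falling and 0 rising, 5 and 1 adjusted within the list). TNFAIP3, which restrains NF-kB, stood at -0.92 ± 0.16 and -0.89 ± 0.16 and the chemokine CXCL1 at -2.26 ± 0.53 and -2.58 ± 0.55. The NF-kB list did not pass in SKMEL173 (adjusted p = 0.0535). In SKMEL30 the sterol (adjusted p = 0.981), lysosome (0.101), neural crest (0.101), unfolded protein response (0.952) and p53 (0.314) lists did not pass. The difference between lines was not tested for lists. G2/M and mitosis genes passed in neither line (medians 0.05 and -0.02, adjusted p = 0.68 and 0.279). Lists were tested with limma's camera (two-sided, preset correlation 0.01) with Benjamini-Hochberg adjustment over the lists of a contrast.

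**Figure D3:**
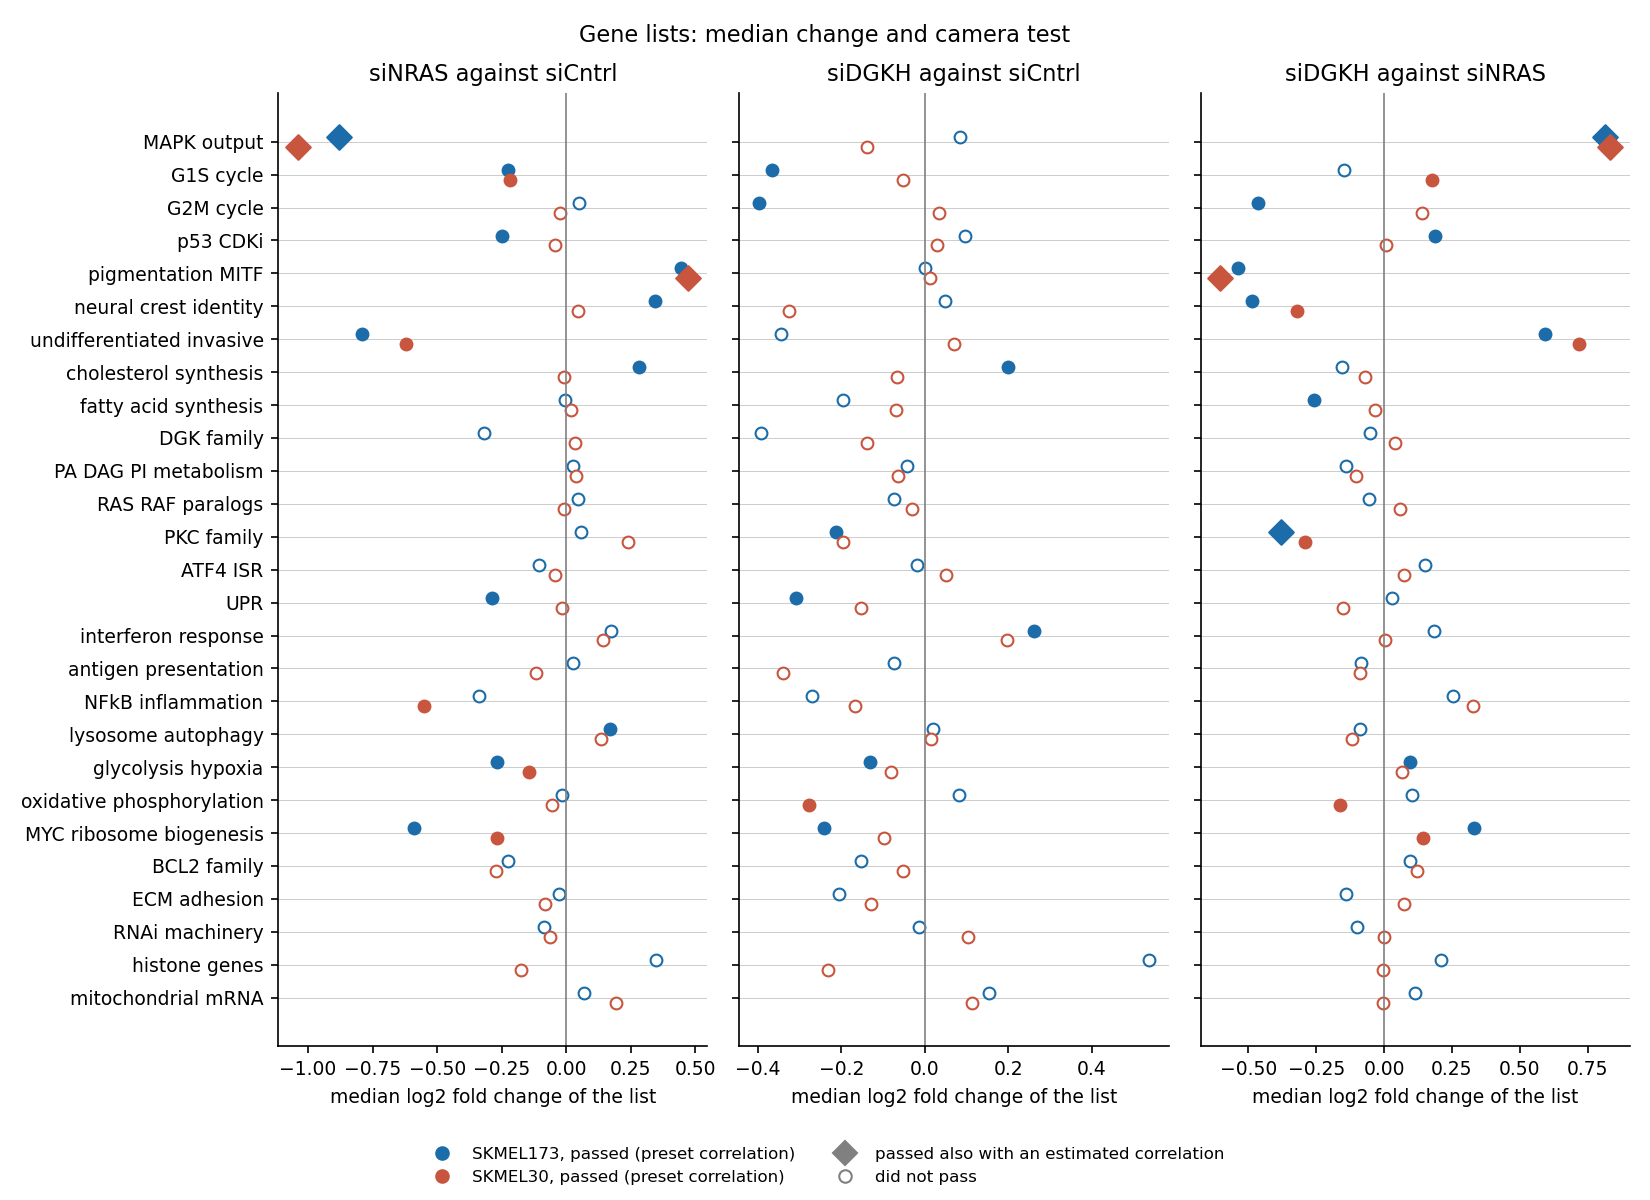
Median log2 change of the 27 fixed gene lists other than cell type markers, in both lines. The panels show siNRAS against siCntrl, siDGKH against siCntrl and siDGKH against siNRAS. Filled symbols passed the list test, and large diamonds also passed it with estimated correlation.

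In counts, siNRAS_05 changed 3202 genes (1378 up, 1824 down) and siNRAS_06 4133 genes (1901 up, 2232 down) in SKMEL173. 2582 genes (1153 up, 1429 down) were called in one direction with both. Of these, 227 rose and 103 fell at least 2-fold. In SKMEL30 the counts were 1931 genes (948 up, 983 down), 2076 genes (1120 up, 956 down) and 1288 genes (704 up, 584 down) with both, 176 up and 117 down at least 2-fold. Both siRNAs called 633 genes (338 up, 295 down) in both lines. With the replicate number as a block the SKMEL173 counts were 5976, 6914 and 4942, with 1182 in both lines. Against Untreated, the counts were 1305, 2183 and 952 in SKMEL173, 316, 991 and 251 in SKMEL30, and 107 in both. In SKMEL30, siNRAS_05 called 1227 genes without its replicate 1 and 1110 without its replicate 2. siNRAS_06 called 1314 and 1307 without its replicates 1 and 2 and 3378 without the short-transcript siCntrl replicate 2. Without both short-transcript libraries the SKMEL30 counts were 2574, 2934 and 1873, with 873 in both lines. Fitted alone with siCntrl, siNRAS_05 called 368 and siNRAS_06 466 genes in SKMEL30. A separate fit of these 3 groups called 529 genes with both siRNAs, and 278 in both lines.

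With the siRNAs against DGKH, of which siDGKH_06 did not pass for DGKH in SKMEL30, a smaller set of genes moved one way with both siRNAs in both lines. TMEM158 changed by log2 -1.57 ± 0.36 and -1.83 ± 0.37 in SKMEL173 and by -1.80 ± 0.30 and -2.30 ± 0.30 in SKMEL30 with siDGKH_05 and siDGKH_06 (± SE, 4 libraries against 4, largest adjusted p = 0.00259). TMEM158 was higher in siCntrl than in Untreated by 0.86 ± 0.35 and 1.69 ± 0.29 (adjusted p = 0.273 and 0.00455). Against Untreated its mean change over the 2 siRNAs was -0.84 in SKMEL173 and -0.36 in SKMEL30 (adjusted p = 0.0474 and 0.505). Without the 2 short-transcript libraries it was -1.43 in SKMEL30 against siCntrl (6.75e-07). YBX3, a cold shock domain protein that binds RNA, changed by -1.02 ± 0.092 and -1.13 ± 0.092 in SKMEL173 and by -1.09 ± 0.12 and -1.01 ± 0.12 in SKMEL30 (3.53e-06). WIPF1, a regulator of actin assembly, changed by -0.86 ± 0.10 and -1.22 ± 0.10 in SKMEL173 and by -0.93 ± 0.18 and -0.86 ± 0.18 in SKMEL30 (0.00193). TCF3, a basic helix-loop-helix transcription factor, changed by -0.85 ± 0.19 and -1.77 ± 0.20 in SKMEL173 and by -0.77 ± 0.17 and -1.65 ± 0.17 in SKMEL30 (0.00499). BCL9, a coactivator of beta-catenin, changed by -1.07 ± 0.17 and -0.75 ± 0.17 in SKMEL173 and by -0.73 ± 0.18 and -0.81 ± 0.18 in SKMEL30 (0.0111). CCN3, a matricellular protein, PLXNA2, a semaphorin receptor, RNF130, SLC10A3 and ABHD17C fell as well.

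Of the genes that rose with both DGKH siRNAs in both lines, PSKH1, a serine kinase, stood at 2.02 ± 0.15 and 1.53 ± 0.15 in SKMEL173 and 1.61 ± 0.14 and 1.23 ± 0.14 in SKMEL30 (largest adjusted p = 1.35e-06). MED20, a Mediator subunit, stood at 1.92 ± 0.13 and 1.69 ± 0.13 in SKMEL173 and 1.47 ± 0.12 and 1.17 ± 0.12 in SKMEL30 (6.9e-07). OXSR1, a kinase of the osmotic stress response, CPEB3, NCEH1, CHORDC1, NECAP1, LMLN, AK9 and SMIM13 rose too. Many of these were lower in siCntrl than in Untreated. PSKH1 stood there at -1.48 ± 0.15 in SKMEL173 and -1.23 ± 0.14 in SKMEL30 (adjusted p = 1.12e-06 and 2.98e-05). MED20 stood at -1.17 ± 0.12 and -0.96 ± 0.12 (2.12e-06 and 0.00017), and OXSR1 at -1.48 ± 0.11 and -1.02 ± 0.17 (2.17e-08 and 0.00276). All 20 genes lay on the called side of the siCntrl mean in all 16 siDGKH libraries. Of them, 14 had no overlap with siCntrl within a line. Against Untreated, 10 of the 10 genes that fell passed in SKMEL173 and 8 in SKMEL30, and 5 and 2 of the 10 that rose (mean of the 2 siRNAs).

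**Figure D4:**
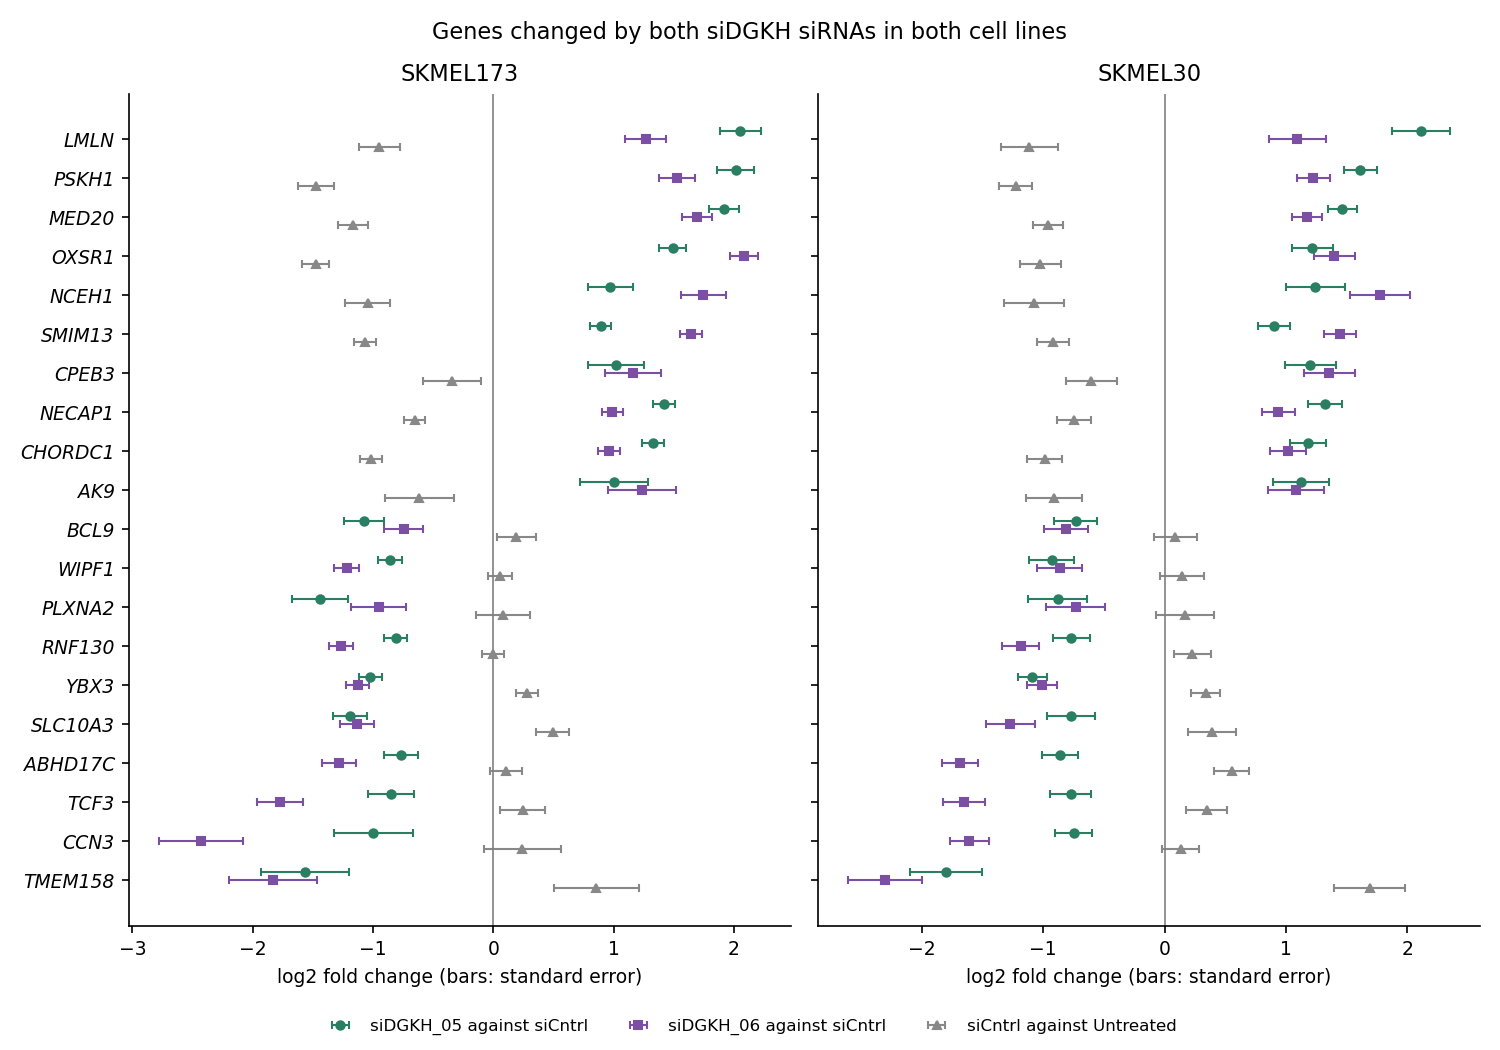
log2 change (± SE, 4 libraries against 4) of the 10 genes that rose most and the 10 that fell most with both DGKH siRNAs in both lines. The change of siCntrl against Untreated is drawn beside the siRNA changes.

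Within SKMEL173, S1PR3, a sphingosine phosphate receptor, changed by -1.65 ± 0.27 and -1.98 ± 0.27 with siDGKH_05 and siDGKH_06. ITGA10, a collagen-binding integrin chain, changed by -1.75 ± 0.30 and -1.50 ± 0.29 and CXCL8 by -3.04 ± 0.60 and -1.41 ± 0.54. GDPD1, a lysophospholipase D, rose by 1.40 ± 0.24 and 1.41 ± 0.24 (largest adjusted p of these = 0.0427). In SKMEL30, KLF2, a zinc finger transcription factor, changed by -1.66 ± 0.28 and -1.70 ± 0.28. KCNN4, a calcium-activated potassium channel, changed by -1.67 ± 0.44 and -1.47 ± 0.43 and PITPNC1, a phosphatidylinositol transfer protein, by -1.23 ± 0.35 and -1.36 ± 0.35. CCNE2, encoding cyclin E2, rose by 1.54 ± 0.14 and 1.54 ± 0.14 (largest adjusted p of these = 0.0279). CCNE2 was lower in siCntrl than in Untreated, as given below, and against Untreated its mean rise was 0.51 (0.0108). All 10 genes taken in SKMEL173 and all 10 in SKMEL30 had their 8 siDGKH libraries on the called side of the siCntrl mean. Against Untreated, 3 of 5 that fell and 3 of 5 that rose passed in SKMEL173, and 1 and 2 in SKMEL30 (mean of the 2 siRNAs). PLEKHB1, up in SKMEL173, then stood at -0.03 (adjusted p = 0.923).

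Among the fixed lists, G1/S and G2/M genes moved down in SKMEL173 when the 2 DGKH siRNAs were averaged. The G1/S list passed (median -0.37, adjusted p = 0.000198, or 0.755 with estimated correlation, with 15 of 26 falling and 2 rising, 17 and 2 adjusted within the list). The G2/M list passed too (median -0.40, adjusted p = 0.000198, or 0.755 with estimated correlation, with 10 of 25 falling and 0 rising, 14 and 0 adjusted within the list). The 2 siRNAs were not alike. The G1/S list had medians 0.16 with siDGKH_05 and -0.96 with siDGKH_06, and the G2/M list medians 0.05 with siDGKH_05 and -0.92 with siDGKH_06. Only 2 and 3 genes fell with both, among them UHRF1 (-0.65 ± 0.17 and -1.43 ± 0.18) and BIRC5, an inhibitor of apoptosis active in mitosis (-1.51 ± 0.17 and -1.41 ± 0.17). MYC and ribosome genes moved down (median -0.24, adjusted p = 0.000977, or 0.755 with estimated correlation, with 12 of 26 falling and 0 rising, 15 and 0 adjusted within the list, none with both siRNAs). The unfolded protein response moved down too (median -0.31, adjusted p = 0.011, or 0.755 with estimated correlation, with 7 of 18 falling and 0 rising, 8 and 0 adjusted within the list). CALR, an ER chaperone, stood at -0.93 ± 0.11 and -0.30 ± 0.11. Glycolysis genes moved down (median -0.13, adjusted p = 0.0249, or 0.755 with estimated correlation, with 10 of 24 falling and 2 rising, 11 and 2 adjusted within the list, medians -0.32 with siDGKH_05 and 0.03 with siDGKH_06). PFKFB4, which controls fructose 2,6-bisphosphate, stood at -0.97 ± 0.17 and -0.46 ± 0.16. Protein kinase C and other diacylglycerol-binding proteins moved down (median -0.21, adjusted p = 0.0387, or 0.432 with estimated correlation, with 6 of 13 falling and 0 rising, 6 and 0 adjusted within the list). CHN1, a RAC GTPase activator, stood at -0.36 ± 0.12 and -0.85 ± 0.13 and PRKD1, encoding protein kinase D1, at -0.53 ± 0.17 and -0.64 ± 0.17.

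Sterol synthesis genes moved up in SKMEL173 (median 0.20, adjusted p = 0.036, or 0.755 with estimated correlation, with 9 of 22 rising and 2 falling, 9 and 2 adjusted within the list). IDI1, an isomerase of the pathway, stood at 0.37 ± 0.13 and 0.82 ± 0.13. Interferon-stimulated genes moved up (median 0.26, adjusted p = 0.0359, or 0.755 with estimated correlation, with 4 of 30 rising and 2 falling, 4 and 2 adjusted within the list, none with both siRNAs). Without replicate 1 the sterol, protein kinase C and interferon lists did not pass (adjusted p = 0.0519, 0.0519 and 0.106, 5 lists in place of 8). Without replicate 2 the protein kinase C list gave adjusted p = 0.0826 and the sterol list 0.0826. Against Untreated the interferon list turned to the other direction (adjusted p = 0.64). In SKMEL30, nuclear genes of the respiratory chain moved down (median -0.28, adjusted p = 0.0499, or 0.952 with estimated correlation, with 4 of 35 falling and 0 rising, 4 and 0 adjusted within the list). UQCRC2, a complex III subunit, stood at -0.37 ± 0.083 and -0.43 ± 0.083. The respiratory chain list was the only one that passed there, and it was higher in siCntrl than in Untreated, as given below. It did not pass without replicate 2 (adjusted p = 0.732, other direction), without the 2 short-transcript libraries (adjusted p = 0.786) or with DESeq2 size factors (adjusted p = 0.0535). The count of lists in SKMEL30 was 1, and 2, 2 and 4 without replicates 1, 2 and 4. ERK-induced genes passed in neither line with siDGKH (medians 0.08 and -0.14, means -0.07 and -0.14, adjusted p = 0.664 and 0.365).

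siDGKH_05 changed 4081 genes (1823 up, 2258 down) and siDGKH_06 6130 genes (2972 up, 3158 down) in SKMEL173. 1472 genes (793 up, 679 down) were called in one direction by both, 76 up and 38 down at least 2-fold. In SKMEL30 the counts were 1323 genes (525 up, 798 down), 3266 genes (1469 up, 1797 down) and 408 genes (225 up, 183 down), 17 up and 19 down at least 2-fold. In all, 259 genes (166 up, 93 down) were called with both siRNAs in both lines. Blocked by replicate number, siDGKH_05 called 6767 genes and both siRNAs 2734 in SKMEL173, and 452 in both lines. Against Untreated 83 genes were called in both lines, and 729 with siDGKH_05 and 148 with both siRNAs in SKMEL30. In SKMEL30, siDGKH_05 called 788 and 835 genes without its replicates 1 and 3. siDGKH_06 called 2116 without its replicate 2. Both siRNAs called 265 and 254 without siDGKH_05 replicates 1 and 3. Without the 2 short-transcript libraries the SKMEL30 counts were 2272, 3603 and 619, with 389 in both lines. Fitted alone with siCntrl, siDGKH_05 called 196 and siDGKH_06 856 genes in SKMEL30. A separate fit of the 3 groups called 159 with both, and 117 in both lines.

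To see how far the 2 siRNAs against a gene gave one response, they were compared with each other. MAGEC1 and SLC7A8 were lower with siNRAS_05 than with siNRAS_06 in SKMEL173 and SKMEL30 (MAGEC1 -2.07 ± 0.11 and -1.57 ± 0.23, adjusted p = 1.56e-11 and 0.00134; SLC7A8 -1.86 ± 0.29 and -1.45 ± 0.16, adjusted p = 0.000969 and 4.97e-05). STX2 and GNAI3 were higher (STX2 0.76 ± 0.095 and 0.87 ± 0.14, adjusted p = 5.26e-05 and 0.00509; GNAI3 0.49 ± 0.092 and 0.44 ± 0.086, adjusted p = 0.00763 and 0.0345). Only 128 genes (38 up, 90 down) in SKMEL173 and 18 genes (4 up, 14 down) in SKMEL30 differed between the siNRAS siRNAs. The siDGKH siRNAs differed in 7148 genes (3552 up, 3596 down) in SKMEL173 and 3387 genes (1676 up, 1711 down) in SKMEL30. PIK3R2, a regulatory subunit of PI3 kinase, was higher with siDGKH_05 than with siDGKH_06 by 3.79 ± 0.47 in SKMEL173 and 2.46 ± 0.37 in SKMEL30 (adjusted p = 7.52e-07 and 3.65e-05), as were CD68 and CITED1. CCN1, a YAP target, was lower with siDGKH_05, at -2.29 ± 0.49 and -2.59 ± 0.39 (0.000548 and 3.35e-05), as was KLF9.

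Across genes, the changes with siNRAS_05 and siNRAS_06 correlated at r = 0.811 in SKMEL173 and 0.829 in SKMEL30. Contrasts without any effect that share the siCntrl libraries give 0.501 and 0.496. For siDGKH_05 and siDGKH_06 r was 0.299 and 0.44 (simulated 0.497 and 0.504) and the covariance 0.0961 and 0.107 (0.0471 and 0.0495). Genes are not independent, so r has no p-value. Against siCntrl the siNRAS siRNAs called 1 gene in SKMEL173 and 0 in SKMEL30 in opposite directions and the siDGKH siRNAs 554 and 78. Blocked by replicate number, the siNRAS siRNAs differed in 468 and 38 genes. The SKMEL173 count was 74, 61 and 75 without siNRAS_05 replicates 1, 3 and 4 and 65 and 71 without siNRAS_06 replicates 1 and 3. The SKMEL30 count was 9 without siNRAS_05 replicate 2. Without the short-transcript libraries the SKMEL30 counts were 40 for siNRAS and 5468 for siDGKH. Fitted with only the groups compared they were 37 and 4 for siNRAS and 5154 for siDGKH in SKMEL30.

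**Figure D5:**
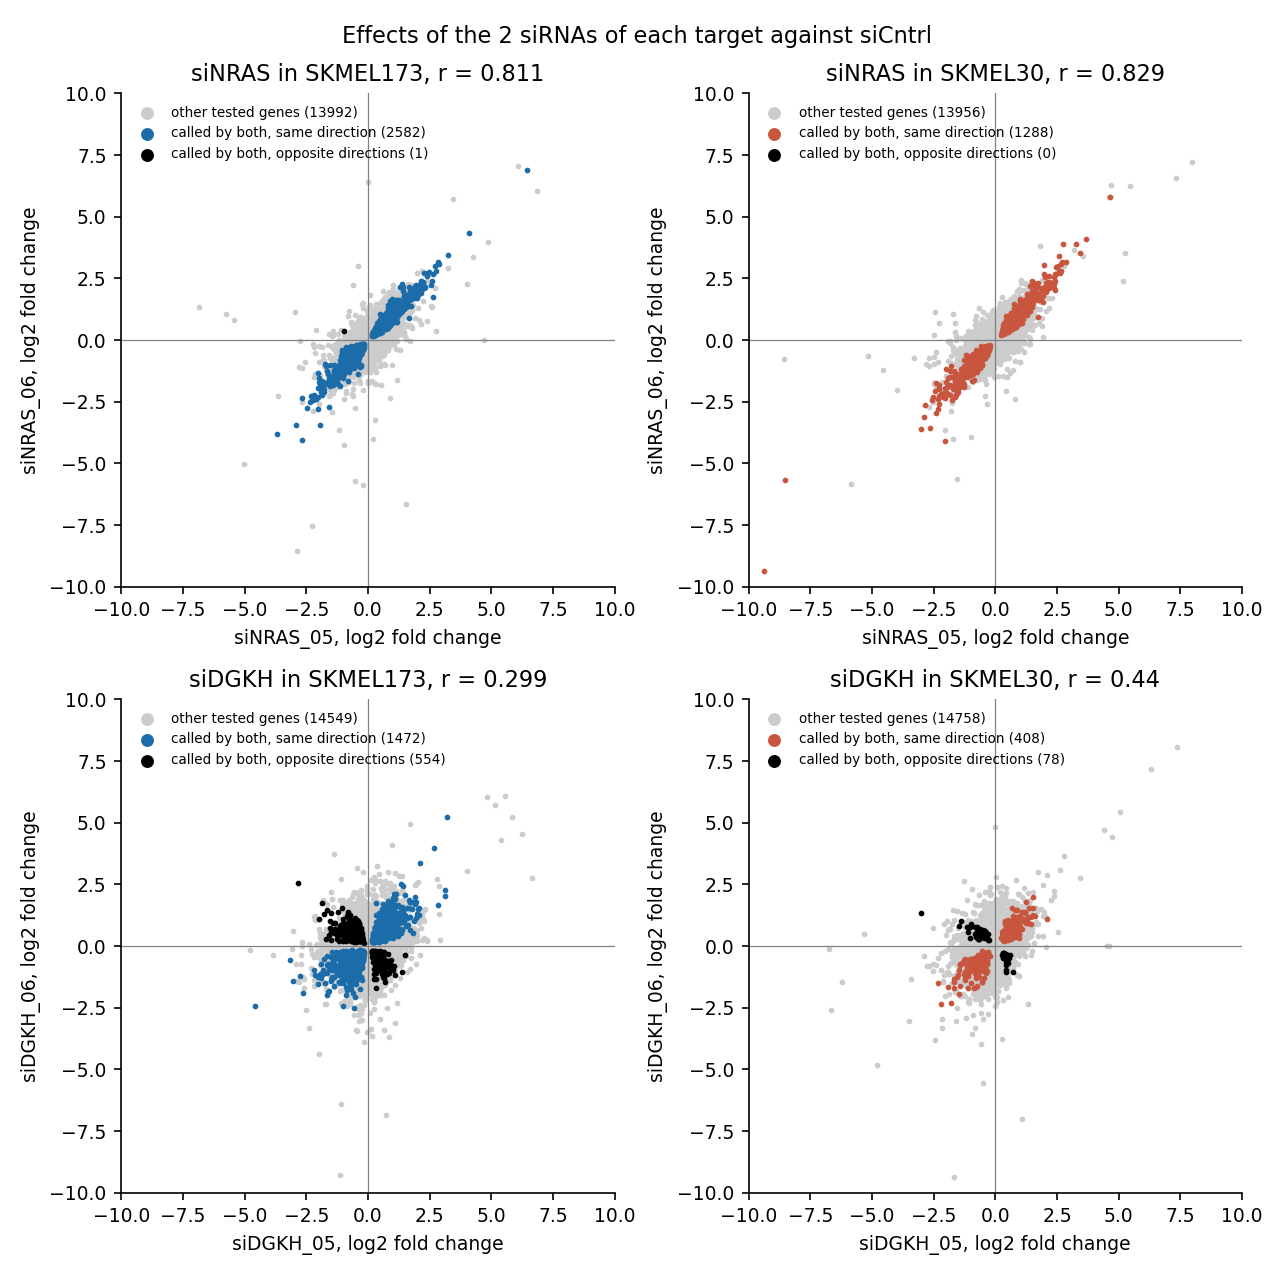
log2 change against siCntrl with siRNA 05 and siRNA 06 for every tested gene, for NRAS and for DGKH in both lines. The correlation across genes and the counts of genes called in one or in opposite directions are printed in each panel.

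siCntrl was compared with Untreated for effects of the control siRNA or the transfection. SLC2A3 was higher with siCntrl by 1.20 ± 0.12 in SKMEL173 and 1.10 ± 0.18 in SKMEL30 (log2 ± SE, 4 libraries against 4, adjusted p = 1.48e-06 and 0.00276). Higher too were PEDS1, an enzyme of plasmalogen synthesis, LMBR1L, TMEM250 and the amino acid transporter SLC43A1. NCEH1 was lower, at -1.04 ± 0.19 and -1.08 ± 0.24 (0.00153 and 0.0305). CCNE2 was lower, at -1.06 ± 0.15 and -1.03 ± 0.14 (0.000146 and 0.000295), and CCNJ at -1.02 ± 0.15 and -1.09 ± 0.22 (0.00014 and 0.0146), beside PSKH1 and OXSR1 given above. For all 10 of these genes the siCntrl and Untreated libraries did not overlap in either line. In the short-transcript siCntrl replicate 2 of SKMEL30, TMEM158 stood at 42.4 CPM against 10.9 to 16.3 in the other siCntrl libraries.

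Interferon-stimulated genes were lower with siCntrl in both lines, with a median of -0.34 in SKMEL173 (adjusted p = 1.79e-05, or 0.797 with estimated correlation). The SKMEL30 median was -0.39 (adjusted p = 0.000303, or 0.681 with estimated correlation). 1 gene in SKMEL173 and 1 in SKMEL30 fell when tested one by one (1 and 6 adjusted within the list). ERK-induced genes were higher in both lines, with a median of 0.20 in SKMEL173 (adjusted p = 0.00299, or 0.388 with estimated correlation). In SKMEL30 it was 0.15 (adjusted p = 0.0101, or 0.708 with estimated correlation). One by one, 1 and 2 rose (1 and 8 adjusted within the list). In SKMEL173, p53 targets were higher (median 0.19, adjusted p = 5.11e-05, or 0.221 with estimated correlation, with 4 of 20 rising and 0 falling, 5 and 0 adjusted within the list). Undifferentiated-state genes (median 0.40, adjusted p = 0.0011, or 0.388 with estimated correlation, with 3 of 20 rising and 0 falling, 6 and 0 adjusted within the list) were higher. So were glycolysis genes (median 0.11, adjusted p = 0.0011, or 0.797 with estimated correlation, with 1 of 24 rising and 0 falling, 2 and 0 adjusted within the list). In SKMEL30, pigment genes were lower (median -0.21, adjusted p = 0.000529, or 0.572 with estimated correlation, with 1 of 21 falling and 0 rising, 4 and 0 adjusted within the list). Respiratory chain genes (median 0.23, adjusted p = 0.01, or 0.829 with estimated correlation), histone genes (median 0.36, adjusted p = 0.0267, or 0.708 with estimated correlation) and the unfolded protein response (median 0.20, adjusted p = 0.037, or 0.829 with estimated correlation) were higher. No gene of these 3 lists passed by itself. Without the 2 short-transcript libraries the last 3 lists gave adjusted p = 0.884, 0.335 and 0.23. In SKMEL30 without replicate 1 the ERK list and the unfolded protein response gave adjusted p = 0.0827 and 0.0827. Without replicate 2 the respiratory chain (other direction) and histone lists gave 0.26 and 0.323. Without replicate 3 the ERK, unfolded protein and histone lists gave 0.0726, 0.0726 and 0.112 (3 lists in place of 6). Without replicate 4 the unfolded protein response gave 0.112. In SKMEL173 8 lists passed without replicate 2 in place of 5.

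siCntrl differed from Untreated in 476 genes (186 up, 290 down) in SKMEL173 and 136 genes (53 up, 83 down) in SKMEL30. With the replicate number as a block the SKMEL173 count was 1854. It was 314 and 285 without siCntrl replicates 1 and 3 and 305 without Untreated replicate 3. The SKMEL30 count was 87 and 248 without siCntrl replicates 1 and 4. It was 67, 78, 66 and 71 without Untreated replicates 1 to 4, and 260 without the short-transcript libraries. Fitted with only these 2 groups, edgeR called 0 genes in SKMEL30. There 2278 genes had an unadjusted p under 0.05 in the fit of all groups and DESeq2 called 374 (741 in SKMEL173).

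The genes called one way with both siRNAs against NRAS and both against DGKH numbered 582 (337 up, 245 down) in SKMEL173 and 145 (90 up, 55 down) in SKMEL30. Independent calls would give 55.2 up and 58.5 down in SKMEL173 and 10.4 and 7.01 in SKMEL30. TMEM158, PSKH1 and MED20 were among them in both lines. All of these contrasts share the siCntrl libraries. The siNRAS and siDGKH changes correlated across genes at r = 0.553 in SKMEL173 and 0.563 in SKMEL30, below the 0.665 and 0.668 of 20 simulations without effect. Their covariance was 0.125 and 0.118 against 0.0474 and 0.0493. With the siCntrl libraries divided between the 2 targets (mean of 6 divisions), r was 0.271 and 0.0977 and the covariance 0.0809 and 0.0284. Then 167 up and 97.3 down were shared in SKMEL173 (independent calls 20 and 23.5) and 33.3 and 27.2 in SKMEL30 (7.45 and 11.7). Against Untreated for both, r was 0.367 and 0.236, with 67 up and 62 down shared in SKMEL173 and 2 and 4 in SKMEL30 (independent calls 11.6 and 18.1, and 0.484 and 0.742). There 17 and 5 were called in opposite directions, and the Untreated libraries are shared. With siCntrl as reference for siNRAS and Untreated for siDGKH, or the reverse, r was 0.0897 and 0.245 in SKMEL173 and -0.12 and 0.0275 in SKMEL30. Blocked by replicate number, 1289 and 255 genes were shared. The SKMEL173 count was 372 without siCntrl replicate 3. The SKMEL30 count was 244 without the short-transcript libraries and 95 fitted with only the groups compared.

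81 genes, 62 up and 19 down, were called one way in all 8 contrasts of an siRNA with siCntrl. They include TMEM158, which fell, and PSKH1, MED20, LMLN, AK9, ACBD5, a peroxisomal protein, CCDC121 and, with the changes of direction given next, OXSR1, SPCS3 and DIP2B, which rose. Against Untreated, OXSR1 stood at -0.19 in SKMEL173 and -0.25 in SKMEL30 with siNRAS (adjusted p = 0.184 and 0.354). SPCS3, a signal peptidase subunit, stood at -0.03 with siNRAS in SKMEL30 (0.933) and DIP2B at -0.001 with siDGKH in SKMEL30 (0.999). Over the 62 genes that rose, the median of a gene's mean change was 0.73 against siCntrl (quartiles 0.61 and 0.88) and 0.15 against Untreated (0.05 and 0.27), with 53 of 62 above 0. Over the 19 that fell it was -0.65 against siCntrl and -0.44 against Untreated (quartiles -0.55 and -0.31), with all 19 below 0. PFKFB4 and MAPKAPK2, a kinase downstream of p38, were called lower in all 8 contrasts against Untreated too. None of the genes that rose was called higher in all 8.

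A direct comparison of the siDGKH with the siNRAS libraries needs neither reference. SLC2A3 was higher with siDGKH than with siNRAS by 1.86 ± 0.090 in SKMEL173 and 1.92 ± 0.13 in SKMEL30 (adjusted p = 1.16e-12 and 6.1e-10) on the log2 scale (± SE, 8 libraries against 8). EGR1 was higher by 2.61 ± 0.18 and 1.80 ± 0.13 (2.37e-10 and 1.7e-09). DKK1 was higher by 1.72 ± 0.17 and 1.96 ± 0.31 (6.56e-08 and 5.2e-05), and so was NRAS itself. TMCC3 was lower, at -2.24 ± 0.46 in SKMEL173 and -3.00 ± 0.26 in SKMEL30 (adjusted p = 0.000435 and 1.74e-08). BCAN was lower, at -2.05 ± 0.30 and -2.12 ± 0.27 (1.13e-05 and 2.79e-06), as were GALNT3, PKNOX2, a homeobox factor, and CITED1, which also differed between the siDGKH siRNAs. All 10 genes taken by the rule had every one of their 16 siDGKH libraries on the called side of the siNRAS mean, and 5 had no overlap.

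ERK-induced genes were higher with siDGKH than with siNRAS, with a median of 0.81 in SKMEL173 (adjusted p = 2.02e-08, or 0.0164 with estimated correlation). It was 0.83 in SKMEL30 (adjusted p = 5.75e-15, or 0.00905 with estimated correlation). 16 and 18 of 22 were higher one by one (18 and 18 adjusted within the list). Pigment genes were lower, with a median of -0.54 in SKMEL173 (adjusted p = 1.62e-05, or 0.353 with estimated correlation). The SKMEL30 median was -0.60 (adjusted p = 1.25e-12, or 0.00588 with estimated correlation). 14 of 20 and 17 of 21 were lower one by one (16 and 17 adjusted within the list). Undifferentiated-state genes were higher, with a median of 0.59 in SKMEL173 (adjusted p = 0.00108, or 0.29 with estimated correlation). In SKMEL30 it was 0.72 (adjusted p = 1.19e-05, or 0.393 with estimated correlation). Neural crest factors were lower, with a median of -0.49 in SKMEL173 (adjusted p = 0.0342, or 0.29 with estimated correlation). It was -0.32 in SKMEL30 (adjusted p = 0.000499, or 0.331 with estimated correlation). MYC and ribosome genes were higher, with a median of 0.33 in SKMEL173 (adjusted p = 4.45e-08, or 0.29 with estimated correlation). The SKMEL30 median was 0.14 (adjusted p = 0.00574, or 0.393 with estimated correlation). Protein kinase C and diacylglycerol-binding proteins were lower, with a median of -0.38 in SKMEL173 (adjusted p = 0.00246, or 0.0258 with estimated correlation). In SKMEL30 it was -0.29 (adjusted p = 0.00827, or 0.393 with estimated correlation).

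In SKMEL173, G2/M genes were lower with siDGKH than with siNRAS (median -0.46, adjusted p = 4.44e-06, or 0.513 with estimated correlation, with 0 of 25 higher and 16 lower, 0 and 18 adjusted within the list). Fatty acid synthesis genes were lower too (median -0.26, adjusted p = 0.039, or 0.506 with estimated correlation, with 0 of 15 higher and 5 lower, 0 and 5 adjusted within the list). p53 targets were higher (median 0.19, adjusted p = 0.00761, or 0.29 with estimated correlation, with 9 of 20 higher and 1 lower, 9 and 1 adjusted within the list), and so were glycolysis genes (median 0.10, adjusted p = 0.0391, or 0.549 with estimated correlation, with 6 of 24 higher and 2 lower, 6 and 2 adjusted within the list). In SKMEL30, G1/S genes were higher (median 0.18, adjusted p = 2.9e-05, or 0.331 with estimated correlation, with 13 of 26 higher and 0 lower, 13 and 0 adjusted within the list). Respiratory chain genes were lower (median -0.16, adjusted p = 0.00439, or 0.761 with estimated correlation, with 0 of 35 higher and 5 lower, 0 and 4 adjusted within the list). Against siCntrl the siDGKH siRNAs were not alike in 3 of these lists. Medians with siDGKH_05 and siDGKH_06 were 0.05 and -0.92 for G2/M and -0.32 and 0.03 for glycolysis in SKMEL173, and 0.16 and -0.22 for G1/S in SKMEL30 (mean of the siNRAS siRNAs 0.05, -0.27 and -0.22). In SKMEL173, fatty acid synthesis did not pass without replicate 1 (adjusted p = 0.0592), neural crest without replicates 2 or 3 (0.0535 and 0.0678) and glycolysis without replicate 3 (0.0678). The comparison called 6276 genes (3101 up, 3175 down) in SKMEL173 and 3949 (1857 up, 2092 down) in SKMEL30 (5638 without the short-transcript libraries). These calls average the siDGKH siRNAs and need not hold for each.

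Finally, each knockdown's effect was compared between lines, as the change in SKMEL173 minus that in SKMEL30. With siNRAS, CEBPD, a C/EBP transcription factor, differed by log2 2.04 ± 0.43 (adjusted p = 0.00899), CEACAM1, an adhesion molecule, by 1.92 ± 0.37 (adjusted p = 0.00348) and RIN2, a RAB5 regulator, by 1.97 ± 0.48 (adjusted p = 0.0285). In the other direction LAMA3, a laminin chain, differed by -2.22 ± 0.50 (adjusted p = 0.0160), HAS2 by -1.77 ± 0.37 (adjusted p = 0.00823) and PHLDB2, a microtubule-anchoring protein, by -1.72 ± 0.27 (adjusted p = 0.000142). NRAS itself fell further in SKMEL173, at a difference of -1.32 ± 0.26 (adjusted p = 0.00462). With siDGKH, PHYHIP differed by 1.41 ± 0.29 (adjusted p = 0.0208), DYRK1B, a kinase, by 1.40 ± 0.29 (adjusted p = 0.0246) and SPP1, encoding osteopontin, by 1.25 ± 0.29 (adjusted p = 0.0486). SLC4A4, a bicarbonate cotransporter, differed in the other direction by -1.58 ± 0.26 (adjusted p = 0.00375), PHLDB2 by -1.42 ± 0.27 (adjusted p = 0.0120) and LRRC8C, an anion channel subunit, by -1.21 ± 0.22 (adjusted p = 0.0120).

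The siNRAS effect differed between lines in 150 genes (69 up, 81 down), or 77 up and 60 down with DESeq2 size factors. The siDGKH effect differed in 44 genes (14 up, 30 down). Blocked by replicate number, the counts were 797 and 588, against Untreated 6 and 11, and fitted with only the groups compared 63 and 1. For siNRAS the count was 96 without SKMEL173 siCntrl replicate 3, 300 without the short-transcript SKMEL30 siCntrl replicate 2 and 295 without both short-transcript libraries. For siDGKH it was 19, 5 and 25 without SKMEL173 siCntrl replicates 1, 3 and 4, and 56 without both short-transcript libraries. It was 22 and 29 without SKMEL173 siDGKH_05 replicates 1 and 3, 121 without SKMEL30 siCntrl replicate 3, 25 without SKMEL30 siDGKH_05 replicate 2 and 22 without SKMEL30 siDGKH_06 replicate 3.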

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

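The tests of transcript length, of the other cell line, of the most abundant genes, of the effect of the control siRNA on the reference, of the siCntrl word in genes picked in SKMEL30 alone, of the words found for the siDGKH siRNAs, of the depth of DGKH knockdown and of the number of changes were chosen after the result was seen, and the bound on opposite calls was changed from a fixed number to a share of the genes called by both after the counts were seen.

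In groups of 4, a library was set apart where its gap to the nearest other exceeded 0.83 of the range (Dixon's rule, met by chance in about 1 in 20 groups), and 4 of 72 group measures met it. TMEM158 stood at 42.4 CPM in SKMEL30 siCntrl replicate 2 (others 10.9 to 16.3). The mean transcript length of that library was 2239 nt (others 2984 to 3094). PSKH1 stood at 21.6 in SKMEL30 siDGKH_06 replicate 2 (others 19.2 to 19.5). Mitochondrial genes held 6.65% of counts in SKMEL30 Untreated replicate 3 (others 5.25 to 5.30%).

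Genes of the naming rule whose effect differed between lines (SKMEL173 minus SKMEL30, log2) were, with siNRAS, CEACAM1 1.92, CEBPD 2.04, HAS2 -1.77, LAMA3 -2.22, MPP4 -2.41, NRAS -1.32, PHLDB2 -1.72, PRCD 2.31, RIN2 1.97, TBC1D30 3.11, TFR2 -4.39, and with siDGKH, DYRK1B 1.40, LPAR3 -0.98, LRRC8C -1.21, MINAR1 -1.08, PHLDB2 -1.42, PHYHIP 1.41, PLEKHB1 1.21, SLC30A1 0.86, SLC4A4 -1.58, SPP1 1.25. PLEKHB1 is one of these although its rise with siDGKH in SKMEL173 turned to -0.03 against Untreated. TBC1D30 was below the count filter in SKMEL173 and PRCD and TFR2 in SKMEL30, so their fitted differences give no bound.

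The 2 short-transcript libraries, SKMEL30 siCntrl replicate 2 and siNRAS_06 replicate 3, were weighed against 3 technical explanations. Over genes, deviation from the rest of the group correlated with transcript length at Spearman rho -0.712 and -0.701 (other SKMEL30 libraries -0.396 to 0.332). As length picked the 2, this is partly circular and only describes a length bias such as partly degraded RNA or library preparation could give. A library of the other line does not account for it, as each correlated better with the SKMEL30 than the SKMEL173 mean by 0.132 and 0.138. Nor do a few genes taking most counts, as the 10 most abundant held 6.92% and 8.32% (others 6.76 to 9.47%). RNA quality is not given in the sources used here, so degradation and preparation were not told apart. The higher TMEM158 in siCntrl replicate 2 is not separable from the bias.

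Of the 62 genes that rose against siCntrl in all 8 contrasts, the median change of siCntrl against Untreated was -0.58 in SKMEL173 and -0.577 in SKMEL30, part of which comes from picking them against the same siCntrl libraries. TGACTAA, the word found for siCntrl (z -15.69 in SKMEL173, -13.43 and rank 3 of 16384 in SKMEL30), lies in the 3′ UTR of 35.5% of them (22 genes) against 7.89% of 11757 others (odds ratio 6.42, Fisher's exact two-sided p = 9.87e-10). This share is partly circular too, because the word and the genes come from the same siCntrl libraries. The word was found in SKMEL173, and of the 88 genes that rose in all contrasts of SKMEL30 with siCntrl, picked without the SKMEL173 libraries, 35.2% hold it against 7.79% of 12159 others (odds ratio 6.44, Fisher's exact p = 3.92e-13). That fits a seed effect of the control siRNA that lowers the reference, though no siRNA sequence is in the labels, and 53 of 62 still had a mean above 0 against Untreated. For the 19 genes that fell, a response shared by both knockdowns was bounded beforehand by calls in all 8 contrasts against Untreated, which 2 met, a result that by that bound speaks against it. The mean over contrasts was below 0 against Untreated for all 19 (median -0.44 against -0.65), and 15 were below 0 in all 8, though the same siRNA libraries picked them. A call asks for more than a direction, so the rule was revised after the values were seen, leaving a shared response open.

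The differences between siDGKH_05 and siDGKH_06 fit off-target seed effects of each siRNA, with words inferred from expression: ATCAACA (z -15.51 and -15.13) and GCCACCA (z -19.52 and -21.95), found in SKMEL173, ranked 1 of 16384 words in SKMEL30, and both lie in 8 of 10 DGKH transcripts. GCCACCA is in 36.9% of the 1130 genes lower with siDGKH_06 in both lines against 15.2% of the others (odds ratio 3.27, Fisher's exact p = 4.42e-63) and ATCAACA in 20.3% of the 1231 lower with siDGKH_05 against 6.36% (odds ratio 3.75, p = 6.17e-51), ratios that are partly circular because the words come from the same libraries. These tests took no account of 3′ UTR length either. A different depth of DGKH knockdown alone does not account for 554 and 78 genes called in opposite directions (1472 and 408 in one direction) in SKMEL173 and SKMEL30, nor for more changes with siDGKH_06, which lowers DGKH less (6130 against 4081 genes, and 3266 against 1323). Nor does lower NRAS with siDGKH_06, as the difference correlated with the siNRAS effect at r = 0.065 in SKMEL30 and -0.086 in SKMEL173. Genes moved one way by both siRNAs could still include effects of DGKH loss, which an siRNA-resistant DGKH would separate.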

How the results depend on the processing

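Directions of the named genes held in most settings. With the replicate number as a block, which pairs libraries of the same number, all 489 calls of named genes and lists kept their direction and stayed past the threshold. The block changed no other call of these, though more genes and lists passed. With DESeq2 size factors 488 of 489 held, with its Wald test 432 of 433, with only the groups compared 387 of 431, and with single libraries left out 5206 of 5336. Against Untreated 218 of 396 held, 156 no longer passed and 22 turned direction. The cause was not tested for any change below.

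With the replicate number as a block the counts were 5976 for siNRAS_05, 6914 for siNRAS_06, 4942 for siNRAS (both siRNAs), 468 for siNRAS_05 against 06, 6767 for siDGKH_05, 2734 for siDGKH (both siRNAs), 1854 for siCntrl against Untreated, 1289 for shared genes in SKMEL173. It gave 38 for siNRAS_05 against 06, 644 for siDGKH (both siRNAs), 369 for siCntrl against Untreated, 255 for shared genes in SKMEL30. It gave 1182 for siNRAS in both lines, 452 for siDGKH in both lines, 797 for the line difference with siNRAS, 588 for the line difference with siDGKH. Against Untreated in place of siCntrl the counts were 1305 for siNRAS_05, 2183 for siNRAS_06, 952 for siNRAS (both siRNAs), 129 for shared genes in SKMEL173. It gave 316 for siNRAS_05, 991 for siNRAS_06, 251 for siNRAS (both siRNAs), 729 for siDGKH_05, 148 for siDGKH (both siRNAs), 6 for shared genes in SKMEL30. It gave 107 for siNRAS in both lines, 83 for siDGKH in both lines, 6 for the line difference with siNRAS, 11 for the line difference with siDGKH. Fitted with only the groups compared the counts were 37 for siNRAS_05 against 06 in SKMEL173. Here a single siRNA was fitted with siCntrl alone and calls with both siRNAs come from a fit of 3 groups. It gave 368 for siNRAS_05, 466 for siNRAS_06, 529 for siNRAS (both siRNAs), 4 for siNRAS_05 against 06, 196 for siDGKH_05, 856 for siDGKH_06, 159 for siDGKH (both siRNAs), 5154 for siDGKH_05 against 06, 0 for siCntrl against Untreated, 95 for shared genes in SKMEL30. It gave 278 for siNRAS in both lines, 117 for siDGKH in both lines, 63 for the line difference with siNRAS, 1 for the line difference with siDGKH. With DESeq2's Wald test the counts were 741 for siCntrl against Untreated in SKMEL173. It gave 60 for siNRAS_05 against 06, 623 for siDGKH (both siRNAs), 374 for siCntrl against Untreated, 220 for shared genes in SKMEL30. It gave 282 for the line difference with siNRAS, 174 for the line difference with siDGKH. Without the low-count filter the counts were 304 for siCntrl against Untreated in SKMEL30. It gave 129 for the line difference with siDGKH. Without the 2 short-transcript libraries (chosen after seeing the data) the counts were 40 for siNRAS_05 against 06, 2272 for siDGKH_05, 619 for siDGKH (both siRNAs), 5468 for siDGKH_05 against 06, 260 for siCntrl against Untreated, 244 for shared genes in SKMEL30. It gave 389 for siDGKH in both lines, 295 for the line difference with siNRAS. Without these 2 libraries and with the block the counts were 3946 for siNRAS_05, 4005 for siNRAS_06, 2705 for siNRAS (both siRNAs), 250 for siNRAS_05 against 06, 3678 for siDGKH_05, 1105 for siDGKH (both siRNAs), 6950 for siDGKH_05 against 06, 852 for siCntrl against Untreated, 6983 for siDGKH against siNRAS, 448 for shared genes in SKMEL30. Without these 2 libraries and against Untreated the counts were 1164 for siNRAS_05, 794 for siNRAS (both siRNAs), 2041 for siDGKH_05, 31 for shared genes in SKMEL30.

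Against Untreated, these named genes turned direction (log2): with siNRAS, CCNE2 -0.4, CYC1 -0.088, MMP14 -0.224, OXSR1 -0.188, SPARC 0.004 in SKMEL173 and CCNE2 -0.15, COL4A2 -0.067, HERC6 -0.017, OXSR1 -0.249, SPCS3 -0.025 in SKMEL30, and with siDGKH, ERAP1 -0.032, LPIN2 -0.164, NEU1 -0.009, PLEKHB1 -0.033, TNFRSF10B 0.016 in SKMEL173 and DIP2B -0.001, LIF 0.195, LPIN2 -0.026, MMP14 -0.019, TRIB3 0.108 in SKMEL30. Only CCNE2 with siNRAS in SKMEL173 passed there (adjusted p = 0.0373). DGKH with siDGKH_06 in SKMEL30 passed without the 2 short-transcript libraries (-0.491, adjusted p = 0.00465). The p53 list with siNRAS and the interferon list with siDGKH in SKMEL173 turned against Untreated (adjusted p = 0.986 and 0.64), and the respiratory chain list turned without replicate 2 in SKMEL30 with siDGKH and for siCntrl against Untreated (0.732 and 0.26). Without replicate 3 that list gave 0.00206 and 0.000288. A 7-mer of siCntrl sought in SKMEL30 instead of SKMEL173 had z -0.27 in the other line, and a 6-mer -19.13.

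Lists that passed with estimated correlation numbered 1 and 2 for siNRAS, 0 and 0 for siDGKH (lowest adjusted p = 0.432 and 0.94), 0 and 0 for siCntrl against Untreated (0.221 and 0.572) and 2 and 2 for siDGKH against siNRAS in SKMEL173 and SKMEL30. In SKMEL30, 13 lists passed for siNRAS and 7 for siDGKH against Untreated, and for siDGKH 3 with the block, 3 without the short-transcript libraries and 0 with DESeq2 size factors (respiratory chain genes, adjusted p = 0.0535).

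Leaving out 1 library at a time (1 replicate number for lists) gave these ranges of the count, or of the log2 change for NRAS and DGKH. For SKMEL173: siNRAS_05 2398 to 3157, siNRAS_06 3055 to 4269, siNRAS (both siRNAs) 1916 to 2637, siNRAS_05 against 06 61 to 120, siDGKH_05 3156 to 4022, siDGKH_06 5036 to 6290, siDGKH (both siRNAs) 1055 to 1521, siDGKH_05 against 06 6171 to 7281, siCntrl against Untreated 285 to 420, siDGKH against siNRAS 5678 to 6491, shared genes 372 to 662. For SKMEL30: siNRAS_05 1110 to 2270, siNRAS_06 1307 to 3378, siNRAS (both siRNAs) 922 to 1645, siNRAS_05 against 06 9 to 20, siDGKH_05 788 to 1732, siDGKH_06 2116 to 3667, siDGKH (both siRNAs) 254 to 528, siDGKH_05 against 06 2543 to 3165, siCntrl against Untreated 66 to 248, siDGKH against siNRAS 3418 to 3952, shared genes 97 to 211. Over both lines: siNRAS in both lines 476 to 753, siDGKH in both lines 176 to 296, the line difference with siNRAS 96 to 300, the line difference with siDGKH 5 to 121. For SKMEL173: NRAS with siNRAS_05 -3.06 to -2.82, NRAS with siNRAS_06 -3.59 to -3.31, DGKH with siDGKH_05 -2.24 to -2.06, DGKH with siDGKH_06 -1.26 to -1.08. For SKMEL30: NRAS with siNRAS_05 -1.76 to -1.38, NRAS with siNRAS_06 -2.54 to -1.93, DGKH with siDGKH_05 -1.26 to -0.826, DGKH with siDGKH_06 -0.502 to -0.072. For SKMEL173: lists for siNRAS 11 to 12, lists for siDGKH 5 to 9, lists for siCntrl against Untreated 5 to 8, lists for siDGKH against siNRAS 8 to 10. For SKMEL30: lists for siNRAS 7 to 8, lists for siDGKH 1 to 4, lists for siCntrl against Untreated 3 to 5, lists for siDGKH against siNRAS 8 to 10.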

Other observations

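All splits and seed-word searches of this part were set before the data were examined, and the count over splits that part 4 pairs was added after the results were seen. Lists that passed in no contrast include some members that moved. In the RNAi machinery, AGO2, the slicer Argonaute, rose with both siDGKH siRNAs (0.75 ± 0.11 and 0.86 ± 0.11 in SKMEL173, 0.73 ± 0.16 and 0.89 ± 0.16 in SKMEL30) and AGO4 with both siNRAS siRNAs (1.55 ± 0.15 and 1.76 ± 0.15 and 1.18 ± 0.19 and 1.27 ± 0.19), while the list's lowest adjusted p over all contrasts was 0.157. In the BCL2 family (lowest adjusted p = 0.0553), PMAIP1, a proapoptotic BH3 protein, stood at -1.53 ± 0.28 and -1.61 ± 0.28 in SKMEL173 and -0.61 ± 0.20 and -1.15 ± 0.21 in SKMEL30 with siNRAS and BCL2L11, encoding BIM, at 0.62 ± 0.16 and 0.82 ± 0.16 in SKMEL30. In the diacylglycerol kinase family (0.114), DGKZ stood at -0.36 ± 0.13 and -0.85 ± 0.13 with siDGKH in SKMEL173.

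The lowest adjusted p was 0.0515 for antigen presentation, 0.0746 for mitochondrial mRNAs, 0.152 for phosphatidic acid and phosphoinositide enzymes, 0.292 for matrix and adhesion, 0.359 for RAS and RAF paralogs and 0.361 for ATF4 targets. Of the markers of other cell types, 3 keratinocyte and 3 leukocyte genes were measured in each line (lowest adjusted p = 0.245 and 0.0746), 4 epithelial genes (0.622), 8 and 5 fibroblast genes (0.174), and 4 endothelial genes in SKMEL173 (0.71) and none in SKMEL30.

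The same search for the siNRAS siRNAs gave GCGAGTA for siNRAS_05 (z -7.09 in SKMEL173, -5.59 in SKMEL30, rank 1479 of 16384) and TGCCCTG for siNRAS_06 (z -8.20 and -3.69, rank 66). Both lie in the NRAS transcript. Genes with GCGAGTA were called lower more often than those without it (32.7 against 13.3% in SKMEL173, 20.8 against 7.24% in SKMEL30), and its 6-mer GCGAGT had z -9.00 in SKMEL30 (rank 430 of 4096). Since other words ranked higher and searches begun in SKMEL30 gave other words, whether these are seed words was left open. A search for siCntrl that began in SKMEL30 gave the 7-mer TTTTAAA (z -0.27 over the genes of SKMEL173, rank 6464), and the 6-mer GACTAA, part of TGACTAA, which ranked 1 in SKMEL173 (z -19.13).

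To test whether chance groupings of the libraries give as many calls, each comparison was fitted alone on every or on random splits of its libraries, with the genes of the main fit (other fits of only the groups compared filtered genes anew). Given are the genes called with the real groups, in brackets the splits with at least as many (the real one included) of all splits and the highest count of any other. In SKMEL173 these were siNRAS_05 2668 (1 of 35, 3), siNRAS_06 3177 (1 of 35, 443), both siNRAS 2320 (1 of 60, 1), siNRAS_05 against 06 34 (2 of 35, 708). For siDGKH they were siDGKH_05 3812 (1 of 35, 1), siDGKH_06 4976 (1 of 35, 0), both siDGKH 1191 (1 of 60, 0), siDGKH_05 against 06 6335 (1 of 35, 0). The rest were siCntrl against Untreated 340 (1 of 35, 17), siDGKH against siNRAS 5829 (1 of 60, 1550), genes shared by siNRAS and siDGKH 519 (1 of 60, 1). In SKMEL30 the siNRAS counts were siNRAS_05 351 (1 of 35, 1), siNRAS_06 454 (1 of 35, 1), both siNRAS 510 (1 of 60, 0), siNRAS_05 against 06 4 (1 of 35, 3). The siDGKH counts there were siDGKH_05 164 (1 of 35, 1), siDGKH_06 795 (1 of 35, 0), both siDGKH 149 (1 of 60, 0), siDGKH_05 against 06 5165 (1 of 35, 0). The others were siCntrl against Untreated 0 (35 of 35, 0), siDGKH against siNRAS 4971 (1 of 60, 1113), genes shared by siNRAS and siDGKH 91 (1 of 60, 0). Over both lines they were both siNRAS 266 (1 of 60, 0), both siDGKH 111 (1 of 60, 0), difference of the siNRAS effect 55 (2 of 40, 303) and difference of the siDGKH effect 1 (3 of 40, 915).

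Other splits gave as many or more calls for siNRAS_05 against siNRAS_06 in SKMEL173, where siNRAS_05 replicates 1, 3 and 4 with siNRAS_06 replicate 4 gave 708, and for both differences between lines. These splits take no account of the replicate number. The split with 708 calls leaves 2 of the 4 pairs of the same number together, and of the 8 splits that part all pairs the highest other count was 0. With the block, 468 genes were called for this comparison and 797 and 588 for the differences between lines, and no splits were fitted with the block, so the splits leave these 3 counts undecided. For siCntrl against Untreated in SKMEL30, edgeR called 0 genes with the real groups fitted alone, so the splits decide nothing there. The 708 calls, several times the real count, point to structure among the samples. Other high counts, such as 443 for siNRAS_06 in SKMEL173 and those for the differences between lines, can carry part of the siRNA effect, which was not tested apart from structure. In splits of 2 groups that part all 4 pairs of the same number, the highest other count was 0, or 1 for siNRAS_05 against siCntrl and for siNRAS_05 against siNRAS_06 in SKMEL30, and 8 splits are too few for a share under 0.05.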
